A study of Homo sapiens with 6 samples.

How the data were processed

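Droplet single-cell RNA sequencing was available for 6 libraries of cortical organoids on day 32 of culture, all derived from 1 human induced pluripotent stem cell line. The labels give a parental library, a library of CBP wild-type genotype, 2 libraries of clones heterozygous for a CBP mutation and 2 libraries of clones homozygous for it. The parental and wild-type libraries, neither labelled as mutant, formed the control group as replicates 1 and 2. The mutant libraries formed the groups CBP_het and CBP_hom, with the clone number as replicate number. The labels do not say which change the mutation is, whether the wild-type library came through the same cloning step, or whether libraries of a group came from separate cultures beyond being separate clones. The p-values therefore measure the spread between these libraries of 1 line.

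Per the labels' protocols, organoids were dissociated with papain and libraries were made from polyadenylated RNA with the Chromium Single Cell 3′ kit, version 3.1. Per the submitters' processing notes, the reads were processed with Cell Ranger against hg38, and per the file headers the matrices were written by Cell Ranger 9.0.1. The annotation version and whether strand was used in counting are not given in the sources used here. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, neither normalized nor restricted to cells: the matrices hold 11383859 barcodes and 38606 genes. Of these genes, 34436 (89.2%) carried an Ensembl identifier of GENCODE 29, a human annotation on GRCh38, from which positions were taken.

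Barcodes were kept as cells with at least 1000 UMIs and at least 10% of the 99th percentile of UMIs among the top 10000 barcodes of the library, at least 500 genes and at most 10% mitochondrial UMIs. The second condition was the one that set the minimum, between 2852.1 and 3828.8 UMIs. The barcodes with the highest Scrublet doublet scores, 0.8% per 1000 barcodes kept, were then removed (7414 barcodes), which left 66196 cells. Cells of all libraries were clustered together without batch integration: values scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 30 clusters. XIST, Y-linked, mitochondrial and ribosomal protein genes were kept out of the variable genes.

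Clusters were named from marker lists fixed before the data were examined, by the mean standardized level of a list over clusters. The scoring rule itself was set after the data were seen: a pan-neuronal score of at least 0.8 for neurons, a score of at least 0.4 for any name, and at least 3 markers at least 2-fold above other cells. A cluster was left unnamed where its leading genes went against the name. Of 9 clusters scoring highest for radial glia, 7 were called radial glia-like. Clusters 13 and 20 were kept out, because a marker of another class and none of their own stood among their 10 leading genes. Cycling progenitors with radial glia markers counted as radial glia-like. No authors' annotation of cells was used here, so these names are rebuilt ones.

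Cells were not treated as replicates. Counts were summed over all cells, or over the cells of a class, within each library and tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in 1 fit of the 3 groups, with TMM normalization, the filterByExpr filter and 3 residual degrees of freedom. The contrasts were CBP_hom minus control, CBP_het minus control and CBP_hom minus CBP_het, each with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Levels are CPM computed here from the deposited counts, scaled to the library total multiplied by its TMM factor and given as mean ± SD of 2 libraries. Where the plain total was used instead, the text says so. Fold changes are on the log2 scale with the standard error (SE) of the fit. Classes were tested where every library had at least 50 cells. Class shares were tested with the same tool on cell counts, with 9 parts (8 named classes and all unnamed clusters as 1 part). A fit of 18 parts, with each unnamed cluster as its own part, had been run first, and the 9-part fit was made the main one after both had been seen. A permutation of 2 against 2 libraries cannot give a p below 0.33, so no permutation p is given.

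Before the data were examined, 43 gene lists were fixed, covering cell type markers, signalling pathways, the cell cycle, stress and metabolism, among others. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, with adjustment over the lists of a contrast. Camera compares a list with the other genes, whereas fry asks whether the genes of a list move, on balance, one way. The same table of choices set which genes are named. In each mutant-control contrast over all cells these were the 10 highest and 10 lowest log2 fold changes. They were taken among genes past the threshold with a mean of at least 10 CPM and no overlap between the libraries of the groups. For CBP_hom minus CBP_het and for each main class the number was 5 and 5. Up to 2 members per list with the smallest adjusted p, or the smallest p where none passed, were added, and CREBBP and EP300 always. XIST, TSIX, Y-linked, mitochondrially encoded and ribosomal protein genes and genes with clone-based names were left out. For a gene with 0 counts in a group the fold is a lower bound against 3 counts per library.

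The tests were tried on simulated counts, for CBP_hom minus control, with 1 mean per gene over the 6 libraries and the libraries' own sizes. Changed genes were drawn only among those with a mean of at least 10 CPM, 67 each at 1.5-fold and 2-fold and 66 at 4-fold. Over all cells (25003 genes), 59.7% of these changed by 1.5-fold and 100% of those changed by 2-fold were called, and 20 unchanged genes were called. In the radial glia-like class (20772 genes) 83.6% of 1.5-fold changes were called, and in the excitatory neuron-like class (16804 genes) 77.6%. The changed list was called and none of the other simulated lists was. Genes were simulated independently of each other, so this does not test lists of correlated genes. For class shares, 35% of 4-fold changes were called and 1% of unchanged classes, so a share that did not pass is weakly informative. Intervals on shares are exact Clopper-Pearson intervals at 95%. Where a library had 0 cells of a class, the limit given is 3 cells of its total instead. Both cover counting error only.

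Alternatives fixed beforehand were DESeq2 1.42.0, no low-count filter, a fit of only the groups compared, a replicate block, leaving out each library, at least 2000 UMIs, at most 20% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2, and values centred within libraries before clustering. Those added after seeing the data were at least 1000 UMIs per cell without the library-specific minimum, only the clusters of a class with at least 100 cells of every library, list tests in those clusters and in the centred clustering, and the 18-part share fit. With a library left out, 2 residual degrees of freedom remained, and the lone library of a group was assumed to vary like the others. Cells were handled in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.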

Results

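Single-cell RNA sequencing of day-32 cortical organoids was compared between 2 control libraries (parental and wild-type), 2 clones heterozygous for a CBP mutation (CBP_het) and 2 clones homozygous for it (CBP_hom). The 66196 cells kept numbered 11099 and 8241 in the parental and wild-type libraries, 13384 and 10624 in CBP_het clones 1 and 2, and 12324 and 10524 in CBP_hom clones 1 and 2. Median UMIs per cell lay between 9916 and 14562, and the median mitochondrial share between 0.952% and 1.384%. In a scaling of the summed counts, the first dimension held 55.4% of the variation and the second 25.3%. The log2 levels of replicates correlated at 0.992 in control, 0.996 in CBP_het and 0.986 in CBP_hom. Replicate counts differed by more than counting error (chi-square per degree of freedom 27.1, 16.4 and 54.2), as separate clones can.

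CREBBP, which encodes the histone acetyltransferase CBP and is the gene named in the labels, was read at similar levels in all groups. Its level was 95.8 ± 3.15 CPM in control, 87.6 ± 0.449 in CBP_het and 89.8 ± 0.514 in CBP_hom (2 libraries each). The differences from control did not pass (CBP_het log2 -0.13, SE 0.05, edgeR adjusted p = 0.12; CBP_hom -0.09, SE 0.05, edgeR adjusted p = 0.285). EP300, which encodes the related acetyltransferase p300, stood at 86.2 ± 2.6 CPM in control, 75.4 ± 2.36 in CBP_het and 77.3 ± 1.55 in CBP_hom. It passed narrowly in CBP_het (log2 -0.19, SE 0.05, edgeR adjusted p = 0.0497) and not in CBP_hom (-0.16, edgeR adjusted p = 0.12). The EP300 call in CBP_het was lost without the parental library (edgeR adjusted p = 0.0881), the wild-type library (0.224), CBP_het clone 1 (0.164) or CBP_het clone 2 (0.312), and also without the low-count filter. Reads were 3′ tags, and tags outside an edited stretch check nothing about it; the labels do not say what the mutation is. CREBBP is ENSG00000005339, on chromosome 16 at 3725054 to 3880726 (minus strand, GRCh38), and EP300 is ENSG00000100393, on chromosome 22 at 41091786 to 41180079 (plus strand).

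The largest difference in the data was in CHCHD2, which encodes a small protein of the mitochondrial intermembrane space. Scaled to the plain UMI total of each library, CHCHD2 was read at 359 CPM in the parental and 487 CPM in the wild-type library, and at 0.234, 0.292, 0.049 and 0.014 CPM in CBP_het clones 1 and 2 and CBP_hom clones 1 and 2. In UMIs these were 41967 and 62214 against 34, 41, 7 and 2. The change from control was -10.66 in CBP_het (SE 0.26, edgeR adjusted p = 0.000147) and -13.63 in CBP_hom (SE 0.32, edgeR adjusted p = 0.000114), and both calls held in every alternative run. The same was seen within classes: radial glia-like cells held 436 ± 72.1 CPM in control against 0.0525 ± 0.0275 in CBP_het and 0.0274 ± 0.0388 in CBP_hom. Excitatory neuron-like cells held 400 ± 60.5 CPM in control, no UMI in CBP_het (at least 972-fold lower) and 0.0471 ± 0.0666 CPM in CBP_hom. Empty droplets of the mutant libraries held 1.07 to 1.92 CPM of their plain totals, more than the cells themselves. CHCHD2 (ENSG00000106153, chromosome 7 at 56101569 to 56106576, minus strand) has processed pseudogenes, and how shared reads were counted is not given in the sources used here.

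**Figure D1:**
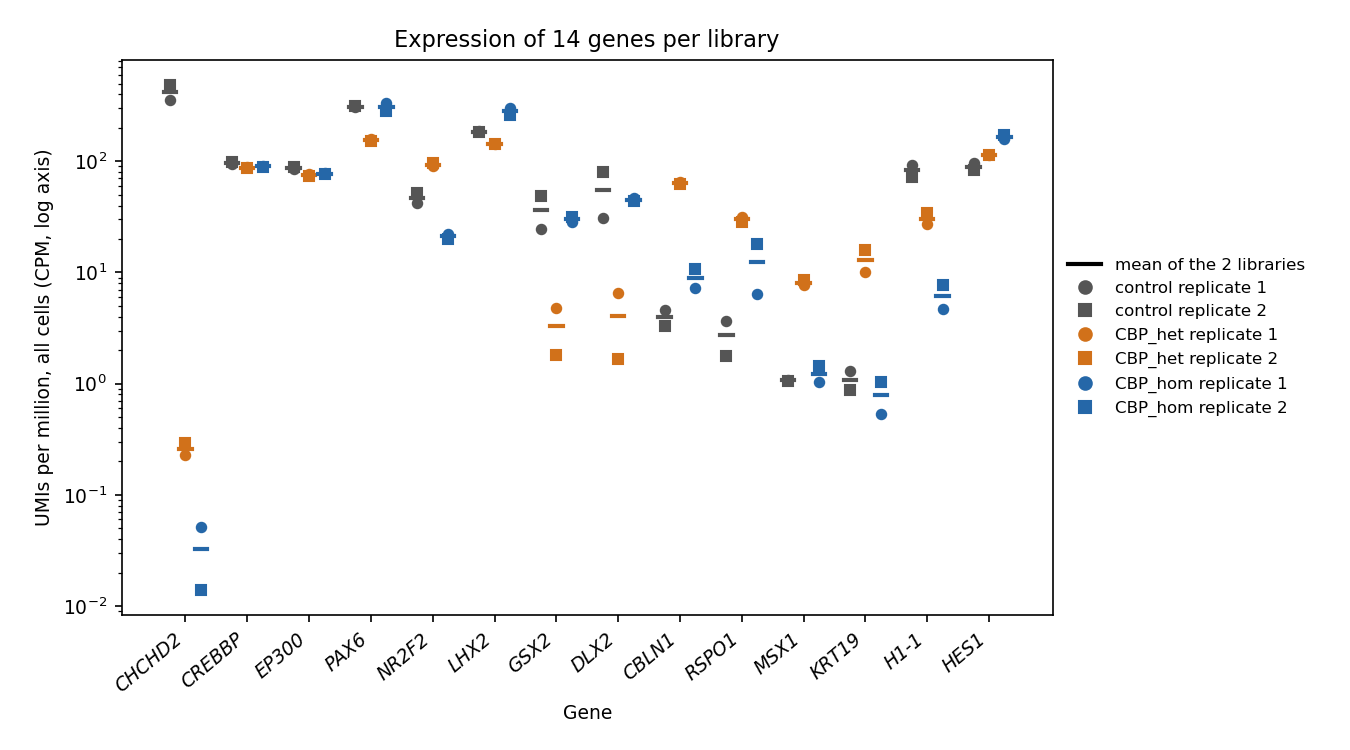
CPM in all cells of each library on a log axis for 14 genes, by group, with bars at the mean of 2 libraries. CHCHD2 fell from 421 CPM in control to 0.26 in CBP_het and 0.0327 in CBP_hom, while CREBBP stayed between 87.6 and 95.8.

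Against control, the genes that fell most in CBP_hom after CHCHD2 included a linker histone, a carboxypeptidase and a potassium channel. The levels that follow are sums over all cells, and change within cells was not separated here from the shares of clusters. H1-1, a replication-dependent linker histone, fell from 82.8 ± 14.6 to 6.17 ± 2.11 CPM (log2 -3.75, SE 0.27, edgeR adjusted p = 0.00495). NAALAD2, a glutamate carboxypeptidase, fell from 27.8 ± 0.415 to 5.33 ± 0.109 CPM (-2.38, SE 0.07, edgeR adjusted p = 0.000227), and KCND2, the channel subunit Kv4.2, from 20.8 ± 1.04 to 5.33 ± 0.296 (-1.96, SE 0.09, edgeR adjusted p = 0.00332). FBN2, a fibrillin of the extracellular matrix, fell by 1.22 (SE 0.10, edgeR adjusted p = 0.00701). NR2F2, a transcription factor of caudal and ventral forebrain, fell from 47 ± 7.35 to 21.2 ± 1.45 CPM (-1.15, SE 0.11, edgeR adjusted p = 0.00791). The imprinted zinc-finger gene PLAGL1 fell by 1.19 (SE 0.07, edgeR adjusted p = 0.00495). HES1, an effector of Notch signalling, rose from 89.5 ± 9.5 to 165 ± 10.5 CPM (0.88, SE 0.09, edgeR adjusted p = 0.00791). These 7 genes held in every alternative, as did the long non-coding ENTPD1-AS1 (-2.30), CCDC144NL-AS1 (-2.37) and LINC03000 (-2.45), which are all annotated as antisense and uncertain because strand use is not given. H1-1 (ENSG00000124610, chromosome 6 at 26017085 to 26017732, minus strand) belongs to a multigene family, which leaves its count uncertain.

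Among 25403 genes tested in all cells, 1187 rose and 859 fell in CBP_hom against control. Of the 69 named genes that passed, 12 held in every alternative. Apart from leaving out single libraries, 20 of the 69 held, and each of the others was lost in a fit of only CBP_hom and control, which called 292 genes (4018 with DESeq2). The total of 2046 was 587 without the parental library, 226 without the wild-type library, 262 and 309 without CBP_het clones 1 and 2, 3608 without CBP_hom clone 1 and 907 without CBP_hom clone 2. Among the named genes whose calls ended with a library left out were LHX2 (0.61, edgeR adjusted p = 0.016; 0.0646 without the parental and 0.0981 without the wild-type library, 0.0591 and 0.0573 without CBP_het clones 1 and 2; lost also in the fit of only CBP_hom and control) and PLXNA4 (-1.12, edgeR adjusted p = 0.00895; 0.0506 without the wild-type library).

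In the gene lists, some genes of the cortical hem, a dorsal signalling centre, rose in CBP_hom against control. The lists were tested on sums over all cells, not separated from the shares of clusters. Leading genes of cluster 20 included RSPO2 of the hem list and FEZF2 and DMRT3 of the forebrain patterning list. Cluster 20 held 0.245% of control and 7.51% of CBP_hom cells, a difference that did not pass (edgeR adjusted p = 0.0636, 18-part fit). Of 10 cortical hem genes, 3 rose, 0 fell and 7 did not pass (5 rose when adjusted over the list alone), with a median log2 fold change of 1.14 (camera adjusted p = 0.00115; adjusted p = 0.766 with an estimated correlation). BMP7, a secreted ligand, rose by 0.37 (SE 0.07, edgeR adjusted p = 0.0316), and WNT8B, a Wnt ligand, was read at 0.00855 CPM in control and 0.259 in CBP_hom (edgeR adjusted p = 0.04). Of 21 genes of the unfolded protein and integrated stress response, 0 rose, 4 fell and 17 did not pass (9 fell over the list alone), median -0.31 (camera adjusted p = 0.00115; adjusted p = 0.766 with an estimated correlation). Stressed cells, whose markers include genes of this response, made up 3.37 ± 1.326% of control and 1.124 ± 0.063% of CBP_hom cells (-1.58, SE 0.48, edgeR adjusted p = 0.16), and the fall in all cells was not separated from that share. ASNS, asparagine synthetase, fell by 1.15 (SE 0.18, edgeR adjusted p = 0.0221) and VLDLR, a lipoprotein and reelin receptor, by 0.71 (SE 0.13, edgeR adjusted p = 0.0293). Of 16 forebrain patterning genes, 7 rose, 1 fell and 8 did not pass (9 and 2 over the list alone), with LHX2 among the risers and NR2F2 falling. Their median was 0.41 (camera adjusted p = 0.00682; adjusted p = 0.766 with an estimated correlation; 0.736 without CBP_hom clone 1). BMP7, WNT8B, ASNS and VLDLR were lost in the fit of only CBP_hom and control, with all their libraries kept, and with libraries left out. Without the wild-type library, CBP_het clone 1 and CBP_het clone 2 in turn, edgeR adjusted p was 0.158, 0.0859 and 0.0839 for BMP7, 0.179, 0.0847 and 0.082 for WNT8B, 0.109, 0.0656 and 0.0648 for ASNS, and 0.118, 0.0827 and 0.0821 for VLDLR. Without CBP_hom clone 2 it was 0.0536, 0.0936, 0.0568 and 0.0853, and without the parental library it was 0.0808 for BMP7 and 0.0945 for WNT8B. In all, 11 of 43 lists passed with the preset correlation, 0 with an estimated one and 0 with fry (19 passed without CBP_hom clone 2). The other 8 were stressed cell markers, cholesterol synthesis, glycolysis, p53 targets and intermediate progenitor markers with lower levels, and G2 and M phase, choroid plexus and mesenchymal genes with higher ones.

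In CBP_het, the MSX genes, ID1, SP5 and KRT19 were among the genes that rose against control, and PAX6, GRIA2, NCAM1 and GSX2 among those that fell. These levels are sums over all cells, and change within cells was not separated from the shares of clusters. CBLN1 was a leading gene of clusters 23 and 26, and ID1 of clusters 24 and 26. Clusters 23 and 26 held 0.8% and 0.364% of control and 11.9% and 2.99% of CBP_het cells. Inhibitory lineage-like cells, with GSX2 among their markers, made up 12.5% and 1.71%. CBLN1, a secreted synapse organizer of the cerebellum, rose from 3.95 ± 0.892 to 63.9 ± 2.55 CPM (log2 4.02, SE 0.23, edgeR adjusted p = 0.00351). MSX1 and MSX2, homeobox targets of BMP signalling, rose from 1.07 ± 0.0216 to 8.1 ± 0.544 CPM (2.92, SE 0.18, edgeR adjusted p = 0.00351) and from 0.146 ± 0.0245 to 7.82 ± 0.133 CPM (5.73, SE 0.32, edgeR adjusted p = 0.00351). ID1, an inhibitor of differentiation induced by BMPs, rose by 3.30 (SE 0.30, edgeR adjusted p = 0.00476), SP5, a target of Wnt signalling, by 5.07 (SE 0.33, edgeR adjusted p = 0.00351), and KRT19, an epithelial keratin, by 3.59 (SE 0.38, edgeR adjusted p = 0.00571). PAX6, a transcription factor of dorsal progenitors, fell from 310 ± 5.86 to 154 ± 4.01 CPM (-1.01, SE 0.09, edgeR adjusted p = 0.00476). GRIA2, a glutamate receptor subunit, fell by 1.58 (SE 0.14, edgeR adjusted p = 0.00476) and NCAM1, a neural adhesion molecule, by 0.83 (SE 0.07, edgeR adjusted p = 0.00476). GSX2, of the ganglionic eminence, fell from 36.8 ± 17.5 to 3.28 ± 2.07 CPM (-3.49, SE 0.50, edgeR adjusted p = 0.00982; 0.0538 without the wild-type library and 0.0551 without CBP_het clone 2).

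In total 3056 genes rose and 2448 fell in CBP_het against control, and of the 98 named genes that passed 21 held in every alternative, all of those in the paragraph above except GSX2 among them. The total of 5504 was 3513 without the parental library, 632 without the wild-type library, 765 and 289 without CBP_het clones 1 and 2, and 6967 and 7127 without CBP_hom clones 1 and 2. MSX1 is ENSG00000163132 (chromosome 4 at 4859666 to 4863936, plus strand), PAX6 is ENSG00000007372 (chromosome 11 at 31784779 to 31818062, minus strand) and CBLN1 is ENSG00000102924 (chromosome 16 at 49277917 to 49281831, minus strand).

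Of the lists, 9 of 10 cortical hem genes rose in CBP_het against control, 0 fell and 1 did not pass (9 over the list alone), among them MSX1 (2.92) and BMP7 (0.71, SE 0.07, edgeR adjusted p = 0.00501). The median was 3.19 (camera adjusted p = 9.0e-13; adjusted p = 0.393 with an estimated correlation). Of 18 BMP and TGF-beta targets, 13 rose, 2 fell and 3 did not pass (14 and 3 over the list alone), led by MSX2, with a median of 1.49 (camera adjusted p = 1.4e-12; adjusted p = 0.393 with an estimated correlation). Of 12 midbrain or hindbrain genes, 9 rose, 0 fell and 3 did not pass (9 over the list alone), median 2.35 (camera adjusted p = 2.8e-07; adjusted p = 0.393 with an estimated correlation). HOXB4, a hindbrain and spinal cord patterning gene, went from 0 counts to 0.37 ± 0.00857 CPM, at least 15.1-fold (edgeR adjusted p = 0.00722; 0.0547 and 0.0628 without CBP_het clones 1 and 2). Of 10 genes of inhibitory neurons or the ganglionic eminence, 0 rose, 9 fell and 1 did not pass (1 and 9 over the list alone), GSX2 among them, median -3.61 (camera adjusted p = 2.8e-07; adjusted p = 0.41 with an estimated correlation). Of 10 pan-neuronal genes, 0 rose, 9 fell and 1 did not pass (9 fell over the list alone), median -0.44 (camera adjusted p = 2.1e-05; adjusted p = 0.393 with an estimated correlation). Of 7 epithelial genes, 5 rose, 0 fell and 2 did not pass (5 over the list alone), KRT8 (2.32) and KRT19 among them, median 1.203 (camera adjusted p = 1.8e-05; adjusted p = 0.393 with an estimated correlation). These lists were tested on sums over all cells, and inhibitory lineage-like cells made up 12.5% of control and 1.71% of CBP_het cells. Choroid plexus-like and mesenchymal-like cells and clusters 20, 23, 26 and 27 had higher shares in CBP_het. The list changes were not separated from these shares. Lists passing numbered 25 of 43 with the preset correlation, 0 with an estimated one and 10 with fry. The axon guidance list and the radial glia list passed as lower (camera adjusted p = 0.00994 for both; adjusted p = 0.393 with an estimated correlation), with medians of only -0.02 and -0.13 over 24 and 11 genes.

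**Figure D2:**
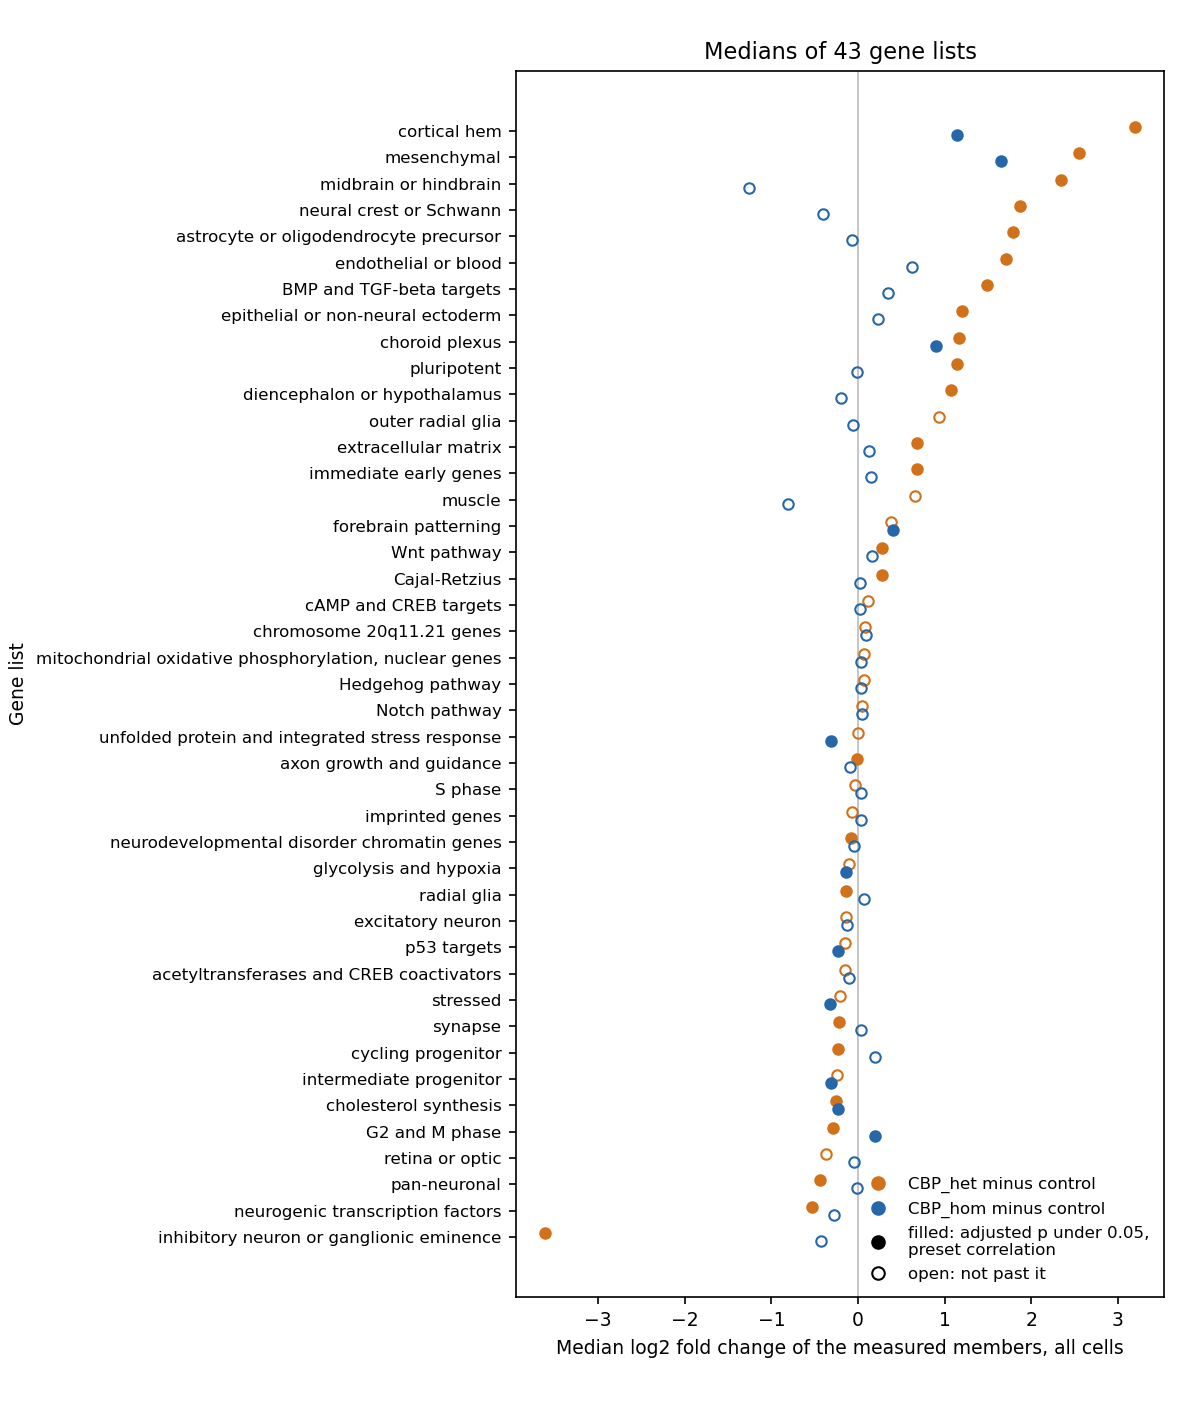
Median log2 fold change of each of 43 gene lists in all cells, CBP_het and CBP_hom against control, with filled points where the camera adjusted p was under 0.05 at the preset correlation. The cortical hem list lay at 3.19 in CBP_het and 1.14 in CBP_hom, and the inhibitory list at -3.61 and -0.43.

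Between the mutant groups, NR2F2 and the MSX genes stood lower in CBP_hom than in CBP_het, and LHX2 and PAX6 higher. NR2F2 was read at 93.2 ± 3.54 CPM in CBP_het and 21.2 ± 1.45 in CBP_hom, on either side of the control level (log2 -2.14, SE 0.12, edgeR adjusted p = 0.00309). MSX1 was lower by 2.72 (SE 0.18, edgeR adjusted p = 0.00371), MSX2 by 3.73 (SE 0.27, edgeR adjusted p = 0.00416) and KRT18, an epithelial keratin with processed pseudogenes, by 2.76 (SE 0.19, edgeR adjusted p = 0.00416). CA2, a carbonic anhydrase of choroid plexus, was lower by 1.02 (SE 0.08, edgeR adjusted p = 0.00516). DKK1, a secreted Wnt inhibitor, was read at 0.677 ± 0.0149 CPM in CBP_het and 0.00717 in CBP_hom (edgeR adjusted p = 0.00416). These 6 genes were the ones that held in every alternative, of 74 named genes that passed. LHX2, a selector gene of cortical identity, was higher in CBP_hom (0.98, SE 0.08, edgeR adjusted p = 0.00517; 0.0588 without CBP_het clone 2), as was PAX6 (0.99, SE 0.09, edgeR adjusted p = 0.0057; 0.0649 without CBP_het clone 2). CRYAB, a small heat-shock protein, was lower (-2.70, SE 0.26, edgeR adjusted p = 0.0061; 0.0571 without CBP_het clone 2). NR2F2 is ENSG00000185551 (chromosome 15 at 96325938 to 96340263, plus strand) and LHX2 is ENSG00000106689 (chromosome 9 at 124001670 to 124033301, plus strand).

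In all cells 1588 genes were higher and 1628 lower in CBP_hom than in CBP_het. Here too change within cells was not separated from the shares of classes and clusters. The total of 3216 was 2509 and 2508 without the parental and wild-type libraries, 425 and 41 without CBP_het clones 1 and 2, and 1662 and 3882 without CBP_hom clones 1 and 2. Of 25 genes of the G2 and M phases, 22 were higher, 0 lower and 3 did not pass (24 over the list alone), median 0.50 (camera adjusted p = 2.2e-16; adjusted p = 0.423 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, was higher by 0.68 (SE 0.09, edgeR adjusted p = 0.0127; 0.0869 and 0.0917 without CBP_het clones 1 and 2), and CDK1, a mitotic kinase, by 0.69 (SE 0.09, edgeR adjusted p = 0.0101; 0.0752 and 0.0867). Of 12 midbrain or hindbrain genes, 0 were higher, 9 lower and 3 did not pass (10 lower over the list alone), with a median of -2.89 or lower, because 2 genes had 0 counts in a group (camera adjusted p = 1.9e-14; adjusted p = 0.33 with an estimated correlation). Of 10 inhibitory or ganglionic eminence genes, 7 were higher, 0 lower and 3 did not pass (9 over the list alone), median 3.13 (camera adjusted p = 2.1e-08; adjusted p = 0.423 with an estimated correlation). GSX2 was higher by 3.19 (SE 0.50, edgeR adjusted p = 0.0161; 0.0837 without CBP_het clone 2). Of 18 BMP and TGF-beta targets, 2 were higher, 11 lower and 5 did not pass (2 and 11 over the list alone), median -1.51 (camera adjusted p = 4.1e-11; adjusted p = 0.423 with an estimated correlation). In all, 24 of 43 lists passed with the preset correlation, 0 with an estimated one and 0 with fry.

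Classes of cells also differed in share between CBP_het and control. Choroid plexus-like cells made up 0.065 ± 0.023% of control and 2.75 ± 0.307% of CBP_het cells (log2 5.36, SE 1.12, edgeR adjusted p = 0.0317), and Cajal-Retzius-like cells 0.892 ± 0.267% and 4.39 ± 0.883% (2.29, SE 0.82, edgeR adjusted p = 0.0489). Mesenchymal-like cells numbered 0 of 11099 and 0 of 8241 in the control libraries, which allows shares of up to 0.027% and 0.0364% (3 cells of the total), and numbered 48 and 92 in the CBP_het libraries (edgeR adjusted p = 0.0433). Inhibitory lineage-like cells made up 12.5 ± 6.51% of control and 1.71 ± 1.36% of CBP_het cells (-2.87, SE 0.80, edgeR adjusted p = 0.0432), and radial glia-like cells 49.2 ± 0.175% and 17.3 ± 2.29% (-1.51, SE 0.47, edgeR adjusted p = 0.0432). Unnamed clusters together held 18.6 ± 6.46% and 62.2 ± 0.732% (1.74, SE 0.53, edgeR adjusted p = 0.0432), and 2 of them scored highest for radial glia, cluster 20 (0.245% of control and 20.2% of CBP_het) and cluster 13. With these 2 included, radial glia-scoring clusters held 50.2% and 49.2% of the control libraries, 36.5% and 40.2% of CBP_het and 61.0% and 53.6% of CBP_hom. In CBP_hom no class passed against control or CBP_het (lowest edgeR adjusted p = 0.16 and 0.0805). Excitatory neuron-like cells made up 11.98 ± 0.457% of control, 5.67 ± 0.11% of CBP_het (edgeR adjusted p = 0.0651) and 9.69 ± 2.83% of CBP_hom cells.

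Every class share that passed depended on single libraries. Without the parental library, the wild-type library, CBP_het clone 1 and CBP_het clone 2 in turn, edgeR adjusted p was 0.106, 0.16, 0.0564 and 0.0711 for choroid plexus-like cells and 0.145, 0.206, 0.194 and 0.159 for Cajal-Retzius-like cells. It was 0.145, 0.16, 0.0788 and 0.159 for mesenchymal-like, 0.106, 0.16, 0.0564 and 0.159 for inhibitory lineage-like, 0.133, 0.16, 0.261 and 0.179 for radial glia-like cells and 0.106, 0.16, 0.194 and 0.159 for unnamed clusters. The choice of cells and clusters mattered as well, with cells clustered and named anew each time. The limit of 20% mitochondrial UMIs could add back only 1 barcode of CBP_het clone 1 and 3 of CBP_het clone 2. That is too few to move a share by itself, so the class names were unstable under new clustering. The radial glia-like call ended at Leiden resolution 2 (log2 -1.045), with values centred within libraries (-0.09), at most 20% mitochondrial UMIs (-0.595), doublets kept (-0.317) or a minimum of 1000 UMIs (-0.332). The Cajal-Retzius-like call ended at resolutions 0.5 (2.108) and 2 (2.111) and with 1000 UMIs (0.835), and its direction reversed with centring (-0.46). The mesenchymal-like call ended at both resolutions, with centring and with 1000 UMIs. Excitatory neuron-like cells passed as lower in CBP_het when either CBP_hom clone was left out (edgeR adjusted p = 0.014 each). Without CBP_hom clone 1, Cajal-Retzius-like and choroid plexus-like cells passed as higher in CBP_hom than in control (edgeR adjusted p = 0.0177 and 0.0133). Without CBP_hom clone 2, radial glia-like (0.0197) and excitatory neuron-like cells (0.0286) passed as higher in CBP_hom than in CBP_het, and choroid plexus-like (0.00541), Cajal-Retzius-like (0.0286) and mesenchymal-like cells (0.032) and unnamed clusters (0.0373) as lower. Whether a fit of 9 or of 18 parts is used also matters, and this was settled after both had been seen. With 18 parts the calls for Cajal-Retzius-like and radial glia-like cells were lost (edgeR adjusted p = 0.0535 each). In that fit, choroid plexus-like and inhibitory lineage-like cells passed between CBP_hom and CBP_het (edgeR adjusted p = 0.0467 and 0.03).

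Unnamed clusters passed in the 18-part fit too, and no cell type is read from them. Higher in CBP_het than in control were clusters 20 and 23 (edgeR adjusted p = 0.0137 each), which held without each library, and clusters 27 (0.0207; 0.0942 without the wild-type library and 0.108 without CBP_het clone 2) and 26 (0.0387). Cluster 26 was lost without the wild-type library (0.102), CBP_het clone 1 (0.0563), CBP_het clone 2 (0.0554) or either CBP_hom clone (0.0522 each). Lower in CBP_hom than in CBP_het were clusters 15, 19, 23 and 27 (edgeR adjusted p = 0.0161 each), 26 (0.0225) and 24 (0.0229). Without CBP_hom clone 1 all of these were lost (0.0826 for clusters 15, 19, 23 and 27, 0.116 for 26 and 0.124 for 24). So were cluster 23 without CBP_het clone 1 (0.0576), cluster 27 without CBP_het clone 2 (0.076) and cluster 24 without CBP_hom clone 2 (0.0533). Some passed only with a library left out. In CBP_hom against control, cluster 20 passed as higher without the parental library (0.0129), the wild-type library (0.0489) or either CBP_het clone (0.00589 each), and cluster 13 without either CBP_het clone (0.00589 each). Clusters 19 and 24 passed as lower there without the wild-type library (0.0489 each) and cluster 14 without CBP_hom clone 1 (0.042). Cluster 15 passed as higher in CBP_het than in control without the parental library (0.0341). Cluster 13 passed as higher in CBP_hom than in CBP_het without the parental or the wild-type library (0.0312 each) or CBP_het clone 1 (0.0335).

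**Figure D3:**
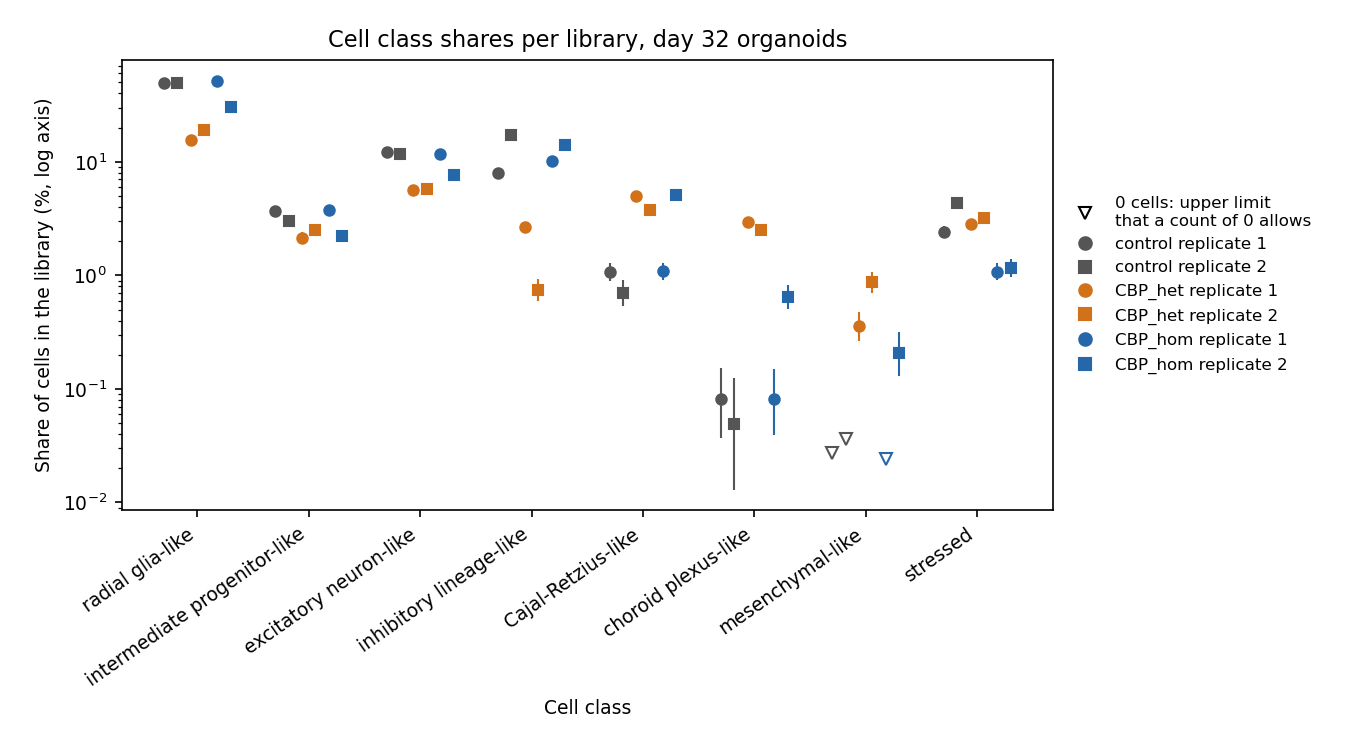
Share of cells in percent on a log axis, by class and library, with Clopper-Pearson intervals and open triangles at the upper limit where a library had 0 cells. Choroid plexus-like cells made up 0.065% of control and 2.75% of CBP_het cells, and inhibitory lineage-like cells 12.5% and 1.71%.

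Among the genes that rose in radial glia-like cells of CBP_het were 2 that act in Wnt signalling. RSPO2, a secreted enhancer of Wnt signalling, rose from 0.504 ± 0.218 to 29.9 ± 1.68 CPM (log2 5.90, SE 0.56, edgeR adjusted p = 0.0018), and WLS, which carries Wnt ligands to the surface, from 2.49 ± 1.61 to 69 ± 6.56 (4.81, SE 0.46, edgeR adjusted p = 0.00183). UNC5C, a netrin receptor, rose by 5.08 (SE 0.39, edgeR adjusted p = 0.00123), and ADAMTS18 and ADAMTSL1, which encode secreted proteins of the ADAMTS family, by 5.62 (SE 0.55, edgeR adjusted p = 0.00189) and 5.33 (SE 0.73, edgeR adjusted p = 0.00381). MGAT4C, a glycosyltransferase, fell from 274 ± 92.3 to 3.61 ± 1.82 CPM (-6.26, SE 0.78, edgeR adjusted p = 0.003). MGAT4C was a leading gene of cluster 5, which held 2200 and 2163 control and 3 and 5 CBP_het cells. ADAMTSL1 and ADAMTS18 were leading genes of cluster 6, which held 24 and 2 control and 621 and 669 CBP_het cells. Part of these differences can therefore lie between clusters of the class. All 6 genes named for CBP_het held in every alternative. In CBP_hom radial glia-like cells, H1-1 fell from 144 ± 25.9 to 9.34 ± 3.14 CPM (-3.96, SE 0.26, edgeR adjusted p = 0.00143) and also held, while ADAMTS18 rose by 3.78 (SE 0.54, edgeR adjusted p = 0.0114; 0.0517 without CBP_het clone 1, and lost also in a fit of only CBP_hom and control). Between the mutant groups, LRRTM3, a synaptic adhesion gene, was higher in CBP_hom (3.39, SE 0.34, edgeR adjusted p = 0.00527; 0.0578 and 0.0705 without CBP_het clones 1 and 2). RSPO2 was lower there (-3.51, SE 0.46, edgeR adjusted p = 0.00893; 0.0944 and 0.0981 without CBP_het clones 1 and 2).

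Of 21143 genes tested in radial glia-like cells, 3391 rose and 3082 fell in CBP_het against control, 1556 rose and 1179 fell in CBP_hom, and 1382 were higher and 1309 lower in CBP_hom than in CBP_het. The CBP_het total of 6473 was 4744, 2457, 1491 and 1462 without the parental, wild-type, CBP_het clone 1 and CBP_het clone 2 libraries and 7510 and 7490 without CBP_hom clones 1 and 2. With values centred within libraries, 4223 of these calls were called again in the same direction and 591 had a fold change of the other sign, called or not, and in the 3 clusters with at least 100 cells of every library 3784 and 314. In the same order of libraries the CBP_hom total of 2735 became 1389, 432, 523, 692, 4196 and 1328, and the total of 2691 between the mutant groups became 2443, 2418, 14, 12, 1427 and 3778. A fit of only CBP_hom and control called 489, and of the calls between the mutant groups 143 had the other sign with centring.

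Cell cycle genes in radial glia-like cells depended on which clusters were compared, because the groups filled different ones. Of the 7 clusters, controls were mostly in clusters 5 (SLC1A3, FBXO32) and 3 (MCM10, DTL), CBP_het in clusters 0 (H1-5, PCLAF) and 6 (OLFM3, ADAMTSL1), and CBP_hom in clusters 4 (ID4, LIX1), 0 and 3. Over all 7 clusters, 22 of 24 S phase genes rose in CBP_het against control, 0 fell and 2 did not pass (23 over the list alone), median 0.49 (camera adjusted p = 8.4e-14; adjusted p = 0.584 with an estimated correlation). Likewise 22 of 25 G2 and M phase genes rose, 0 fell and 3 did not pass (24 over the list alone), median 0.52 (camera adjusted p = 2.8e-08; adjusted p = 0.641 with an estimated correlation). An alternative chosen after seeing the data took the 3 clusters with at least 100 cells of every library. There 19 of the 25 G2 and M phase genes fell, median -0.34 (camera adjusted p = 5.1e-09). The S phase list did not pass (0.115, camera adjusted p = 0.158). These 3 clusters are led by cell-cycle genes (H1-5, TOP2A and CDC20). Values within them therefore cannot show whether cycling rose or fell in the class. With values centred within libraries before clustering the medians were -0.51 for G2 and M phase (24 of 25 fell, camera adjusted p = 7.0e-19) and -0.27 for S phase (camera adjusted p = 0.000517). In CBP_hom against control, 14 of 25 G2 and M phase genes rose, 0 fell and 11 did not pass (25 over the list alone), median 0.50 (camera adjusted p = 3.7e-11; adjusted p = 0.668 with an estimated correlation), but not in the shared clusters (0.06, camera adjusted p = 0.154). So no change in cycling within radial glia-like cells is claimed from these lists. The cortical hem list rose in CBP_het in both forms, with 5 of 8 genes up and 3 not passing over all clusters (6 over the list alone; median 3.02, camera adjusted p = 1.8e-06; adjusted p = 0.584 with an estimated correlation) and 7 of 7 up in the shared clusters (3.77, camera adjusted p = 1.3e-07).

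**Figure D4:**
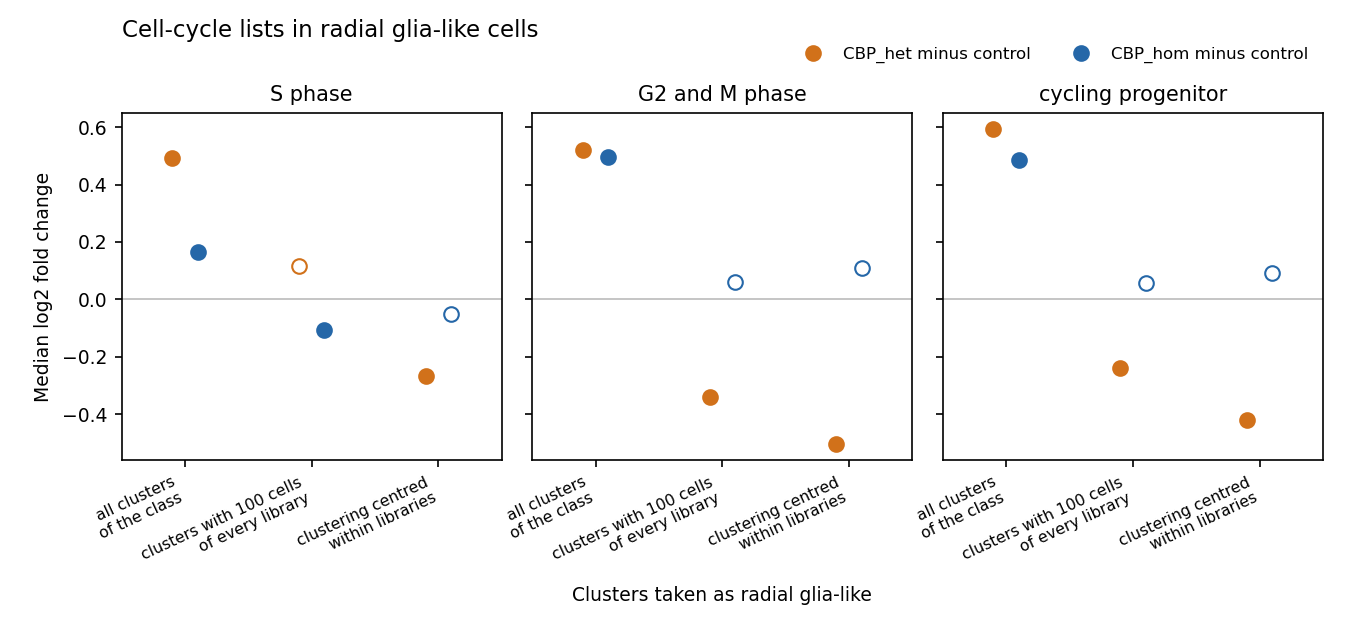
Median log2 fold change of S phase, G2 and M phase and cycling progenitor lists in radial glia-like cells, by the clusters taken, with filled points where the camera adjusted p was under 0.05. In CBP_het against control the G2 and M phase median was 0.52 over all clusters and -0.34 in clusters with 100 cells of every library. The latter clusters are themselves led by cell-cycle genes.

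Of 21 cholesterol synthesis genes, 0 rose, 9 fell and 12 did not pass in radial glia-like cells of CBP_hom against control (1 and 13 over the list alone). Their median was -0.32 (camera adjusted p = 6.1e-06, adjusted p = 0.668 with an estimated correlation). In the shared clusters 7 fell (-0.24, camera adjusted p = 0.000377). Lists passing in radial glia-like cells numbered 13 of 41 in CBP_het against control, 11 in CBP_hom against control and 8 between the mutant groups with the preset correlation, 0 in each with an estimated one, and 1 in each with fry. These counts reached 22 without the parental library for CBP_het, 17 without the parental, 6 without the wild-type and 7 without the CBP_hom clone 1 library for CBP_hom, and 15 without CBP_hom clone 2 between the mutant groups.

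In excitatory neuron-like cells both mutant groups shared several changes from control. ANKRD7, an ankyrin repeat gene, rose from 1.31 ± 1.04 CPM to 20.4 ± 3.72 in CBP_het (log2 3.99, SE 0.35, edgeR adjusted p = 0.000574) and 18.6 ± 1.84 in CBP_hom (3.85, SE 0.34, edgeR adjusted p = 0.000911). TCERG1L, a homologue of a transcription elongation regulator, rose from 0.936 ± 1.12 CPM to 12.6 ± 1.5 (3.79, SE 0.53, edgeR adjusted p = 0.0019) and 18.9 ± 5.48 (4.39, SE 0.49, edgeR adjusted p = 0.00203). TNNI1, a troponin of slow muscle, rose by 2.35 in CBP_hom (SE 0.19, edgeR adjusted p = 0.000669), and the adrenergic receptor gene ADRA1A fell there by 2.54 (SE 0.27, edgeR adjusted p = 0.00172). In CBP_het, PAX7, a dorsal midbrain and muscle transcription factor, rose from 3.1 ± 2.28 to 31.1 ± 2.66 CPM (3.35, SE 0.46, edgeR adjusted p = 0.00184), and TNNT1, another slow troponin, by 3.77 (SE 0.49, edgeR adjusted p = 0.0016). All of these held in every alternative. Between the mutant groups, FOXP2, a transcription factor of deep cortical layers, was higher in CBP_hom (636 ± 192 against 200.5 ± 60 CPM; 1.67, SE 0.22, edgeR adjusted p = 0.00733; 0.11 and 0.0635 without CBP_het clones 1 and 2). FOXP2 is a leading gene of cluster 16, which held 72 and 102 cells of CBP_het clones 1 and 2, 544 and 229 of CBP_hom clones 1 and 2 and 586 and 436 of the control libraries. The rest of the class was cluster 8, with 677 and 509, 897 and 580, and 780 and 525 cells. In cluster 8 alone the FOXP2 difference was 1.136 and passed, but genes called between the mutant groups numbered 310 there, against 1400 in the class. PLAAT3, a phospholipase, was lower by 2.08 (SE 0.21, edgeR adjusted p = 0.00446; 0.0937 and 0.0658 without CBP_het clones 1 and 2).

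Glycolysis and hypoxia genes rose in excitatory neuron-like cells of CBP_het: of 23, 16 rose, 0 fell and 7 did not pass (21 over the list alone), median 0.51 (camera adjusted p = 1.4e-09; adjusted p = 0.488 with an estimated correlation). Cholesterol synthesis genes fell: of 20, 0 rose, 11 fell and 9 did not pass (14 over the list alone), median -0.44 (camera adjusted p = 9.5e-06; adjusted p = 0.472 with an estimated correlation). Synapse genes fell too: of 24, 0 rose, 13 fell and 11 did not pass (1 and 16 over the list alone), median -0.32 (camera adjusted p = 0.000316; adjusted p = 0.472 with an estimated correlation). In cluster 8, the EOMES- and TBR1-expressing cluster with at least 100 cells of every library, the glycolysis and cholesterol lists passed the same way (0.27, camera adjusted p = 1.4e-05, and -0.61, camera adjusted p = 3.0e-10) and the synapse list did not (camera adjusted p = 0.849). Between the mutant groups, 8 of 20 cholesterol genes were higher in CBP_hom, 0 lower and 12 did not pass (16 over the list alone), median 0.35 (camera adjusted p = 4.1e-09; adjusted p = 0.388 with an estimated correlation). In CBP_hom against control only the oxidative phosphorylation list passed, with 4 of 24 genes up, 0 down and 20 not passing (5 over the list alone), median 0.12 (camera adjusted p = 0.0405; adjusted p = 0.959 with an estimated correlation). It was lost without the wild-type library (0.266), CBP_het clone 1 (0.0869), CBP_het clone 2 (0.079) or CBP_hom clone 1 (0.206), and in cluster 8 alone (median 0.08, camera adjusted p = 0.245), where 5 other lists passed. Lists passing numbered 15 of 40 in CBP_het against control (9 without the parental library and 8 without CBP_het clone 2) and 14 between the mutant groups. With an estimated correlation 0 passed in any of the 3 contrasts, and with fry 10, 0 and 0 passed in CBP_het against control, CBP_hom against control and between the mutant groups.

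Of 17163 genes tested in excitatory neuron-like cells, 2130 rose and 2026 fell in CBP_het against control, 850 rose and 557 fell in CBP_hom, and 760 were higher and 640 lower in CBP_hom than in CBP_het. The CBP_het total of 4156 was 2275, 1612, 1150 and 1588 without the parental, wild-type, CBP_het clone 1 and CBP_het clone 2 libraries and 5181 and 5177 without CBP_hom clones 1 and 2. In the same order the CBP_hom total of 1407 became 666, 213, 687, 671, 2752 and 943. The total of 1400 between the mutant groups became 920, 897, 0 (2736 in edgeR at unadjusted p under 0.05), 5, 706 and 2537. It was 294 and 171 at Leiden resolutions 0.5 and 2, 828 in a fit of only the mutant groups and 2593 without the low-count filter. For CBP_hom against control a fit of only these groups called 573, and 2726 were called without the filter. For CBP_het against control DESeq2 called 2660, resolution 2 gave 2106, and cluster 8 alone gave 2448, with the other sign for 151 of the calls of the class.

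Genes also passed in the other classes tested. In Cajal-Retzius-like cells (14747 genes) 1627 rose and 1255 fell in CBP_het against control, and 151 rose and 165 fell in CBP_hom. In inhibitory lineage-like cells (16697 genes) the counts were 235 and 127 in CBP_het and 267 and 122 in CBP_hom, with 0 called by edgeR between the mutant groups (1384 at unadjusted p under 0.05). In intermediate progenitor-like cells (13249 genes) they were 1442 and 1284 in CBP_het and 702 and 796 in CBP_hom, and in stressed cells (14251 genes) 903 and 722 and then 570 and 355. Between CBP_hom and CBP_het, 894 genes were higher and 1267 lower in Cajal-Retzius-like, 286 and 360 in intermediate progenitor-like and 48 and 46 in stressed cells. These classes were not run with libraries left out or in shared clusters, and their clusters were filled unevenly, so part of these calls can come from the clusters. Of the Cajal-Retzius-like clusters, 9 held 113 and 58 control, 419 and 220 CBP_het and 126 and 501 CBP_hom cells, and 28 held 7 and 0, 252 and 180, and 8 and 34. Cluster 18 of the intermediate progenitor-like class held 17 and 28 control cells and 0 in each mutant library.

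The mutant groups moved together against control more often than apart. In all cells 678 genes rose in both CBP_het and CBP_hom, 415 fell in both, CHCHD2, KCND2 and NAALAD2 among them, and 50 moved in opposite directions, NR2F2 among them. Independent lists of these sizes would share 142.8, 82.8 and 217.7 genes. The log2 fold changes correlated at 0.601 over 25403 genes, against 0.517 (0.478 to 0.533) in 20 simulations without any change, where the shared controls alone give a correlation. The covariance was 0.311 against a simulated 0.0425. Both contrasts used the same 2 control libraries, too few to give each contrast 2 of its own, so part of the excess may come from the shared controls.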

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

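Except for that on the clusters that hold the excitatory neuron-like class, the tests in this part were chosen only after the results they measure had been seen. The results listed first were picked out because the mutant groups, both compared with the same controls, differed from each other in a test or moved to opposite sides of control.

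NR2F2 stood at 93.2 CPM in CBP_het and 21.2 in CBP_hom, with control at 47, a log2 difference between the mutant groups of -2.14 (edgeR adjusted p = 0.00309). LHX2 stood at 143 CPM in CBP_het and 281 in CBP_hom, with control at 184 (0.98, edgeR adjusted p = 0.00517). CRYAB stood at 7.13 CPM in CBP_het and 1.1 in CBP_hom, with control at 3.42 (-2.70, edgeR adjusted p = 0.0061). The list of G2 and M phase genes lay below control in CBP_het, with a median of -0.29, and above it in CBP_hom, with 0.20, a median difference in all cells of 0.50 (camera adjusted p = 2.2e-16; adjusted p = 0.423 with an estimated correlation). Radial glia-like cells made up 17.3% of CBP_het, 40.9% of CBP_hom and 49.2% of control cells. Dividing cells also lay outside this class, as in unnamed cluster 26 (MKI67 at 515.5 CPM of the plain total), with 428 and 296 CBP_het, 15 and 37 CBP_hom and 66 and 11 control cells. Within radial glia-like cells the list had medians of 0.52 in CBP_het and 0.50 in CBP_hom over all clusters of the class. In its clusters with 100 cells of every library they were -0.34 and 0.06. Those clusters are themselves led by cell-cycle genes, so these values cannot settle a change in cycling. The difference in all cells is not read as one in cycling. For LHX2 and CRYAB the call between the mutant groups ended without CBP_het clone 2 (edgeR adjusted p = 0.0588 and 0.0571).

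CHCHD2 lay near 0 in all 4 mutant libraries and at 359 and 487 CPM of the plain totals in control. Against loss of a chromosome segment that takes in the genes before CHCHD2, the 9 measured neighbours within 2 Mb had a median log2 change of -0.213 in CBP_het and -0.281 in CBP_hom, and the lowest were VOPP1 (-0.787) and ZNF713 (-0.525). All 9 lie at lower coordinates, so a loss that runs only from CHCHD2 to higher ones stays open, with 0 measured genes on that side. Against a shift in cell class makeup, the highest level in any mutant library over 6 classes was 0.217% of the lower control library, and against a level graded with the number of mutant CBP copies, the CBP_het mean was already 0.0622% of the control mean. Below that level CHCHD2 was lower in CBP_hom than in CBP_het (-2.97, SE 0.59, edgeR adjusted p = 0.0277), a call lost without CBP_het clone 1 (0.087), CBP_het clone 2 (0.143), CBP_hom clone 1 (0.062) or CBP_hom clone 2 (0.0899), so a grading within the last traces stays open. Most of the CBP_het UMIs of CHCHD2 lay in cells outside these 6 classes. Radial glia-like cells held 2 and 1 UMIs in CBP_het clones 1 and 2 and 4 and 0 in CBP_hom clones 1 and 2, too few to show a grading there. An on or off state that the mutant clones inherited, apart from CBP, cannot be told apart from an effect of CBP: 0 groups held both high and near-0 libraries, and the labels do not say whether the wild-type library went through the same cloning step. Reads shared with processed pseudogenes were not tested, and neither was a DNA change at CHCHD2 itself.

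More genes were called in CBP_het than in CBP_hom against control, 2.69 times as many in all cells. Without CBP_het clone 2 the gap was not seen in all cells, but it was seen in radial glia-like cells. That fit left CBP_het with 1 library against 2 of CBP_hom. Its spread came only from the control and CBP_hom pairs. The CBP_het pair was the closest (chi-square per degree of freedom 16.45, against 27.12 in control and 54.16 in CBP_hom). Counts without a CBP_het clone therefore cannot show that the gap rests on that clone. The size of the gap also varied widely. In all cells DESeq2 called 6228 in CBP_het and 4018 in CBP_hom, and fits of only the 2 groups compared 7037 and 292. Counts were 3513 and 587 without the parental library, 632 and 226 without the wild-type library, 765 and 262 without CBP_het clone 1, 6967 and 3608 without CBP_hom clone 1 and 7127 and 907 without CBP_hom clone 2. Deeper sequencing of the CBP_het libraries was argued against by the UMIs in cells, which were 1.005 times those of CBP_hom. In radial glia-like clusters with 100 cells of every library the ratio of calls was 2.289. In the excitatory neuron-like cluster with 100 cells of every library it was 1.791. So the gap did not rest on unevenly filled clusters alone. Those 3 radial glia-like clusters are led by cell-cycle genes (H1-5, TOP2A and CDC20) and may pool different progenitors. A shift in makeup within them therefore stays open. Opposite moves of the 2 CBP_hom clones that cancel in their mean cannot be told apart from a smaller effect, because the farther CBP_hom library lay 0.942 times as far from control as the nearer CBP_het library, between the bounds set (0.1305 and 0.1588 for CBP_hom, 0.1685 and 0.1764 for CBP_het, median absolute log2 difference over 9656 genes). The genotype itself stays open, as does chance between 2 clones a group.

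In excitatory neuron-like cells, 247 genes at a mean of at least 10 CPM were raised at least 2-fold in CBP_het, ANKRD7, PAX7 and TNNT1 among them. Free RNA from other cells was argued against, since 96.0% of these genes rose by more than free RNA at a share of 0.215 would give, a share taken from 11 radial glia genes. Different clusters holding the class in the groups was argued against as well: 95.5% of the genes were called up, and all were higher, in the cluster with 100 cells of every library. That cluster held 677 and 509 of the 749 and 611 CBP_het cells of the class, so mostly the same CBP_het cells chose the genes. It held 780 and 525 of the 1366 and 961 control cells. A difference in the maturity of neurons within that cluster was not tested, and the CBP genotype stays open.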

How the results depend on the processing

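Of the alternatives in this part, the minimum of 1000 UMIs, the clusters with 100 cells of every library, the lists in those clusters and in the centred clustering, and the 18-part share fit were chosen only after the results had been seen. All others were fixed before the data were examined. Where a result changed, the cause was not tested.

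Apart from leaving out libraries, named genes kept their result in 1928 comparisons, weakened in 97, strengthened in 4 and reversed in 2: in the cluster with 100 cells of every library, HS6ST3 in excitatory neuron-like cells of CBP_het against control went to 1.348 and CSMD1 between CBP_hom and CBP_het to -0.036. The losses sat mostly in CBP_hom against control, where 20 of 69 called genes held in all cells and 2 of 10 in radial glia-like cells. Each of the others there was lost in the fit of only the groups compared. With a library left out, 1245 stayed, 651 weakened and 6 strengthened. A minimum of 2000 UMIs lay below the minimum of every library, removed no cell and tests nothing, so it is left out of these tallies.

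Counts of genes changed stayed within 1.5 times in 45 of the alternatives without a library left out. In CBP_hom against control, DESeq2 called 4018 genes in all cells. A fit of only the groups compared called 292 in all cells, 489 in radial glia-like and 573 in excitatory neuron-like cells there, and 828 in excitatory neuron-like cells between the mutant groups. Without the low-count filter excitatory neuron-like cells gave 2726 in CBP_hom against control and 2593 between the mutant groups. In excitatory neuron-like cells of CBP_het against control, DESeq2 called 2660, Leiden resolution 2 gave 2106, and the cluster with 100 cells of every library 2448. Between the mutant groups that class gave 294 at resolution 0.5, 171 at resolution 2 and 310 in the cluster with 100 cells of every library. The clone numbers are shared between the mutant groups without any stated link, and the deviations of the first clones from their group means correlated at -0.093 over 10252 genes. With the replicate block, the count between CBP_hom and CBP_het was 2099 in all cells (897 higher, 1202 lower), 1694 in radial glia-like and 952 in excitatory neuron-like cells, and lists passing numbered 23, 8 and 15. With each library left out, genes changed in all cells ranged from 226 to 3608 (CBP_hom against control), 289 to 7127 (CBP_het against control) and 41 to 3882 (between the mutant groups). In radial glia-like cells the ranges were 432 to 4196, 1462 to 7510 and 12 to 3778, and in excitatory neuron-like cells 213 to 2752, 1150 to 5181 and 0 (edgeR, 2736 at unadjusted p under 0.05) to 2537. Centred within libraries, the excitatory neuron-like class had under 50 cells in a library and was not run.

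With an estimated correlation, 0 lists passed (camera) in any of the 9 tests. With fry, 0, 10 and 0 passed in all cells (CBP_hom and CBP_het against control, and between them), 1, 1 and 1 in radial glia-like and 0, 10 and 0 in excitatory neuron-like cells. In the clusters with 100 cells of every library, 6 passed in radial glia-like cells of CBP_hom against control, and 5, 9 and 7 in excitatory neuron-like cells. Centred within libraries, 15 passed in radial glia-like cells between the mutant groups. In radial glia-like cells 7 list results reversed. In clusters with 100 cells of every library, themselves led by cell-cycle genes, S phase reversed in CBP_hom against control (camera adjusted p = 0.0402). In CBP_het against control cycling progenitor (camera adjusted p = 0.00452) and G2 and M phase (camera adjusted p = 5.12e-09) reversed there. Centred within libraries the reversed lists were cycling progenitor (camera adjusted p = 8.94e-08), S phase (camera adjusted p = 0.000517) and G2 and M phase (camera adjusted p = 6.97e-19) in CBP_het against control. Between the mutant groups S phase reversed with centring (camera adjusted p = 0.000499). With each library left out, lists passing ranged from 12 to 19 in all cells (CBP_hom against control). In radial glia-like cells they ranged from 6 to 17, 13 to 22 (CBP_het against control) and 6 to 15 (between the mutant groups), and in excitatory neuron-like cells from 0 to 6 and 8 to 18 (CBP_het against control).

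Class shares moved with the clustering, with the cell filters, each followed by new clustering and naming, and with the parts of the fit. The limit of 20% mitochondrial UMIs could add back only 1 and 3 barcodes of CBP_het clones 1 and 2, too few to move a share by themselves. The values that follow are log2 differences. In CBP_het against control, the Cajal-Retzius-like call was lost at resolutions 0.5 (2.108) and 2 (2.111), with 1000 UMIs (0.835) and in the 18-part fit (2.295), and reversed with centring (-0.46). The radial glia-like call was lost at resolution 2 (-1.045), with centring (-0.09), at most 20% mitochondrial UMIs (-0.595), doublets kept (-0.317), 1000 UMIs (-0.332) and 18 parts (-1.507). The choice between 9 and 18 parts was made after both had been seen. The mesenchymal-like call was lost at both resolutions (9.077 each), with centring (9.061) and with 1000 UMIs (9.046), sizes set by 0 cells in control. Excitatory neuron-like cells passed as lower at resolution 2 (-1.986), with centring (-6.899), 20% mitochondrial UMIs (-2.244), doublets kept (-1.061) and 1000 UMIs (-2.099), and stressed cells with centring (-1.459). Between CBP_hom and CBP_het, the 18-part fit passed choroid plexus-like (-2.921) and inhibitory lineage-like cells (2.827), and centring and 1000 UMIs passed inhibitory lineage-like (2.25 and 2.439) and excitatory neuron-like cells (6.838 and 1.69). The stressed share reversed with centring (1.458).

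With each library left out, the log2 share differences in CBP_het against control ranged from 2.02 to 2.639 for Cajal-Retzius-like, 5.065 to 5.791 for choroid plexus-like, -1.117 to -1.039 for excitatory neuron-like, -4.068 to -2.208 for inhibitory lineage-like, 8.321 to 9.517 for mesenchymal-like and -1.649 to -1.378 for radial glia-like cells. In CBP_hom against control they ranged from 0.28 to 2.504 for Cajal-Retzius-like and 0.288 to 3.263 for choroid plexus-like cells, which passed without CBP_hom clone 1. Between the mutant groups they ranged from -2.013 to 0.211 (Cajal-Retzius-like), -5.064 to -2.087 (choroid plexus-like), 0.438 to 1.043 (excitatory neuron-like), -9.086 to -1.537 (mesenchymal-like) and 0.822 to 1.563 (radial glia-like). Beyond these, depth limited genes with few counts, such as DKK1 and WNT8B, for which no fold is given.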

Other observations

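The tests in this part were fixed before the data were examined. In all cells of CBP_het against control, the single genes OLIG2, OLIG1, NPPC, ZNRF3 and PLXNA4 held in every alternative. OLIG2 and OLIG1, transcription factors of oligodendrocyte and ventral progenitors, rose from 0.249 ± 0.0343 to 1.23 ± 0.0596 CPM (log2 2.31, SE 0.19, edgeR adjusted p = 0.00439) and from 0.152 ± 0.0507 to 1.35 ± 0.21 CPM (3.15, SE 0.35, edgeR adjusted p = 0.00577). NPPC, a natriuretic peptide, rose by 3.10 (SE 0.22, edgeR adjusted p = 0.00351), and ZNRF3, a ligase that dampens Wnt signalling, by 0.94 (SE 0.07, edgeR adjusted p = 0.00378). PLXNA4, a semaphorin receptor, fell by 1.39 (SE 0.12, edgeR adjusted p = 0.00468). These levels and the lists that follow come from sums over all cells, not separated from the shares of classes and clusters. NPPC was a leading gene of cluster 24. Of 8 neural crest or Schwann cell genes, 6 rose, 0 fell and 2 did not pass (6 over the list alone), median 1.88 (camera adjusted p = 4.8e-05; adjusted p = 0.393 with an estimated correlation). Of 10 mesenchymal genes, 6 rose, 0 fell and 4 did not pass (9 over the list alone), median 2.55 (camera adjusted p = 3.4e-05; adjusted p = 0.5 with an estimated correlation). COL1A2, a fibrillar collagen among them, rose from 27.8 ± 11 to 166 ± 12.4 CPM (2.58, SE 0.43, edgeR adjusted p = 0.0135), a call that ended without the wild-type library (0.0903), CBP_het clone 1 (0.0618) or CBP_het clone 2 (0.0747).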
